A study of Homo sapiens with 12 samples.

How the data were processed

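RNA was sequenced from 12 libraries of 2 neuroblastoma lines. Per the labels' protocols, libraries were made from 3 µg of RNA with a NEBNext Ultra RNA kit, and per the submitters' processing notes HISAT2 2.0.5 and featureCounts 1.5.0-p3 were used and the genome build was mm10. The deposited table gives FPKM per gene and library, with gene symbol, biotype, length and coordinates. All 58735 genes of the table are human Ensembl genes, and the start and end of all 58735 equal those of GENCODE release 29 on GRCh38, so coordinates are given on that build, and the mm10 entry is not used. Whether counting used strand is not given in the sources used here, so reads of overlapping antisense genes cannot be told apart.

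The depth behind the FPKM values was worked out from the values. FPKM times gene length was a whole multiple of one step in each library for 100% of values, with a tolerance of 0.05 reads, which gives whole reads per gene and 15425460 to 19249018 reads per library. The step showed that the authors' FPKM was scaled by a denominator in exact proportion to median-of-ratios size factors of the reads, not to library totals (the ratio to the size factors was 1 in every library, and the ratio to the totals ran from 0.924 to 1.08). Levels are therefore relative to that scaling. A gene with 0 reads in a group is given with the level that 3 reads over the group would equal, and folds against such a group are lower bounds. These floors cover counting error only.

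Groups were taken from the sample titles and the genotype label before the data were examined, as were the gene lists, the tests, the rule for named genes and most alternatives. The deposited FPKM values were analysed as log2(FPKM + 1) with limma 3.58.1 in R 4.3.3. Genes with a mean FPKM of at least 0.5 over all 12 libraries were tested (15856 genes). One model with 4 group means was fitted to all 12 libraries, so that groups share one estimate of the spread, with empirical Bayes moderation and an intensity trend. P-values are two-sided and were adjusted by Benjamini-Hochberg within each comparison, and 0.05 was the threshold. Fold changes on the log2(FPKM + 1) scale understate the change of low genes, so levels in FPKM are given and folds in the text are ratios of mean FPKM. Counts of genes changed at least 2-fold instead take an absolute log2 fold of at least 1 on the scale of the model. That scale is log2(FPKM + 1) unless another setting is named. The comparisons were knockdown against control in each labelled line, the difference of these effects between lines, and control against control. A table of all columns was mapped by sample title, and 0 columns belonged to no sample.

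The text names TSPYL5, G3BP1, RANBP2, MYCN, CDKN1A and MDM2 in each knockdown comparison whatever their result. It also names the 5 largest rises and 5 largest falls per knockdown comparison whose libraries do not overlap between groups, up to 2 members of each gene list past the threshold with the largest fold, and the 5 genes in each direction with the largest smaller fold in both lines. For the difference between lines it names the 5 most positive and 5 most negative genes, and for the control libraries up to 2 members of each identity list. Some genes that the rule takes are not reported here. There were 21 gene lists with 536 symbols in all, fixed before the data were examined: p53 targets, stemness, noradrenergic, mesenchymal and neuronal identity, matrix and EMT, G2/M, S phase, MYC targets and ribosome biogenesis, interferon, unfolded protein and amino acid stress, hypoxia and glycolysis, cholesterol synthesis, stress granule with SUMO and nuclear pore, the TSPY and NAP family, immediate early genes, markers of Schwann, epithelial, and blood and endothelial cells, mitochondrial transcripts and ribosomal proteins. Older symbols were matched through a table of gene names. Lists were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation and with fry. Calls in the list counts are those over all genes tested.

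The steps were tested on simulated libraries drawn from the real group means, with about 50 genes changed at each fold. For SK-N-SH knockdown against control the model recovered 44.0% of genes changed 1.5-fold, 91.8% of those changed 2-fold and 100% of those changed 4-fold among 15798 genes, with 6.40% false calls. For the second line it recovered 38.0%, 91.8% and 100% among 15818 genes, with 4.88% false calls. For SK-N-SH knockdown against second line control it recovered 42.0%, 87.8% and 96.0% among 15893 genes, with 5.08% false calls, and for second line knockdown against SK-N-SH control 51.0%, 91.8% and 100% among 16011 genes, with 7.69% false calls. Of genes changed 1.25-fold the model recovered 2.00%, 6.00%, 0% and 2.00% in these comparisons, in the order given. Of 20 lists with no change, camera called 1 in the last of these simulations and 0 in the others. Genes were drawn independently in the simulations, while the estimated correlation of the real lists reached 0.852. False list calls under such correlation were therefore not tested. Replicates were compared by a chi-square of their reads per gene, which ran from 3.63 to 21.2 per degree of freedom, above counting error alone. It ran from 3.85 to 3.97 in second line control and from 5.68 to 21.2 in second line knockdown. The simulations used a single preset dispersion for all groups, so false calls under such unequal spread were not tested. Technical replicates can also differ by more than counting error, so the chi-square does not show separate cultures. Each library was counted as a separate sample.

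The alternatives tried were a pseudocount of 0.1, no filter on low values and a minimum mean FPKM of 2, equal FPKM sums, quantile normalization, each line fitted alone, no intensity trend, array weights, a replicate block, protein-coding genes alone and leaving out each library in turn. Median-of-ratios scaling was planned too. It moves nothing here, since the authors' scaling already has that form. A count model on the recovered reads was planned and not run, because the deposited unit is FPKM, and limma's voom on the recovered reads was added in its place after the data were seen. After the expression levels of the groups were seen, each knockdown group was also compared with the control group of the other label. Figures were drawn with matplotlib 3.10.9.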

Results

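Transcript levels were measured by RNA sequencing in 12 libraries from 2 human neuroblastoma lines, cultured tumour cells of the sympathetic nervous system. Each line carried either a control short hairpin RNA or a hairpin directed against TSPYL5, a member of the TSPY and NAP family of histone-binding proteins, and each of the 4 groups held 3 libraries. The study was about the part TSPYL5 plays in stem-cell properties of neuroblastoma and in modification of p53 through G3BP1, a stress granule protein, and RanBP2, a nuclear pore protein that acts in SUMO conjugation. The first line is called SK-N-SH in every label. The second line is SK_N_BE2 in the sample titles and SH-SY5Y in the other labels, so it is called the second line here. Whole reads recovered from the deposited FPKM came to 18014544 to 18909666 per library in SK-N-SH control, 15542671 to 16355217 in SK-N-SH knockdown, 15425460 to 16459726 in second line control and 18282551 to 19249018 in second line knockdown. Mitochondrial genes took 6.25% to 8.23% of these reads. The labels do not say whether replicates were separate cultures, so the p-values measure only the spread between these libraries, which can be technical. Values below are mean FPKM ± SD with n = 3 libraries per group, and adjusted p-values are from limma with Benjamini-Hochberg adjustment.

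TSPYL5, on chromosome 8 from 97273474 to 97277964 of GRCh38 on the minus strand (ENSG00000180543), did not follow the knockdown label in both lines. Its FPKM was 13.1, 13.4 and 12.2 in the 3 SK-N-SH control libraries and 17.1, 18.3 and 17.8 in the 3 libraries labelled SK-N-SH knockdown. In the second line it was 24.0, 24.4 and 25.8 in the controls and 13.3, 12.4 and 12.6 in the libraries labelled knockdown. The log2 fold of knockdown over control was 0.43 (SE 0.05, limma adjusted p = 7.45e-06) in SK-N-SH, higher in 3 of 3 libraries, and -0.90 (SE 0.05, adjusted p = 9.86e-09) in the second line, lower in 3 of 3. Because the target gene went against its label in SK-N-SH, every group below is named by its label only. MYCN, the oncogene amplified in a subset of neuroblastomas (chromosome 2, 15940564 to 15947007, plus strand, ENSG00000134323), stood at 0.0408 ± 0.0407 FPKM in SK-N-SH control and 1028 ± 49.0 in the libraries labelled SK-N-SH knockdown. In the second line it stood at 1040.4 ± 33.3 in control and had 0 reads in all 3 libraries labelled knockdown, where 3 reads over the group would equal 0.0218 FPKM.

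The libraries correlated by expression across the labelled lines rather than within them. Across the 15856 genes tested, which are not independent replicates, Pearson's r of log2(FPKM + 1) was 0.986 to 0.987 between libraries labelled SK-N-SH knockdown and second line control. It was 0.960 to 0.975 between second line knockdown and SK-N-SH control. Within the labelled lines, control and knockdown libraries correlated at 0.705 to 0.724 in SK-N-SH and at 0.692 to 0.721 in the second line, while replicates of one group correlated at 0.987 to 0.992.

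**Figure D1:**
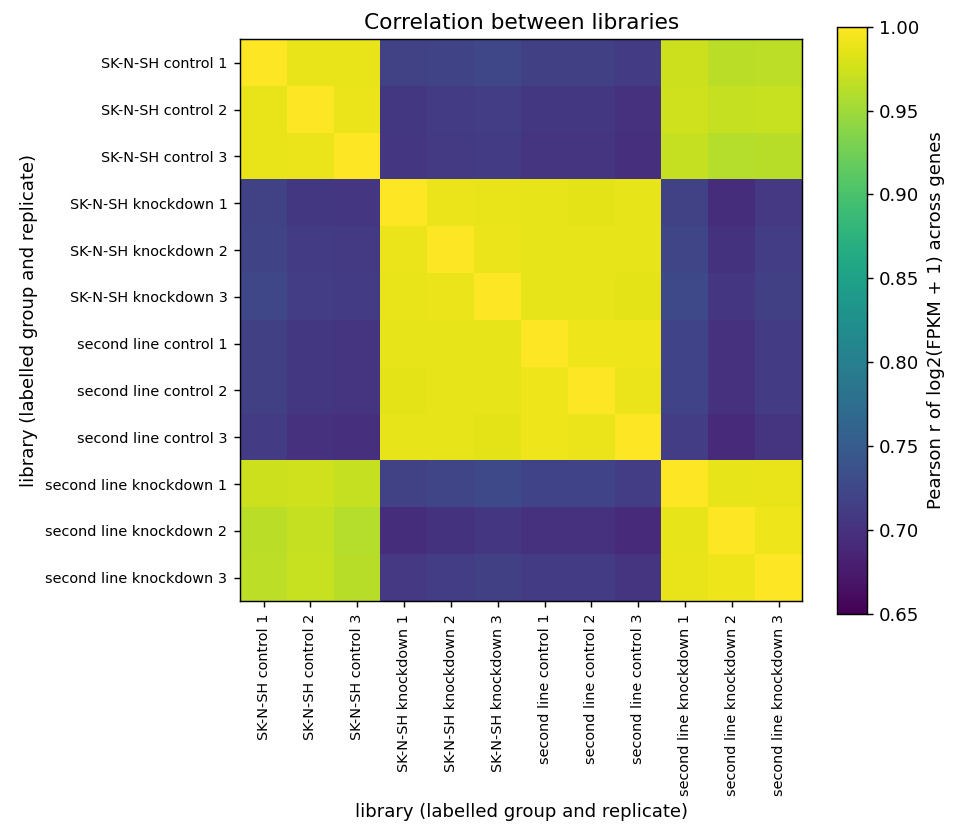
Pearson correlation of log2(FPKM + 1) across 15856 genes between all 12 libraries, ordered by labelled group and replicate on both axes, with colour giving r. The libraries labelled SK-N-SH knockdown and second line control share one block of high correlation (0.986 to 0.987 between the groups), and SK-N-SH control and second line knockdown share another (0.960 to 0.975).

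**Figure D2:**
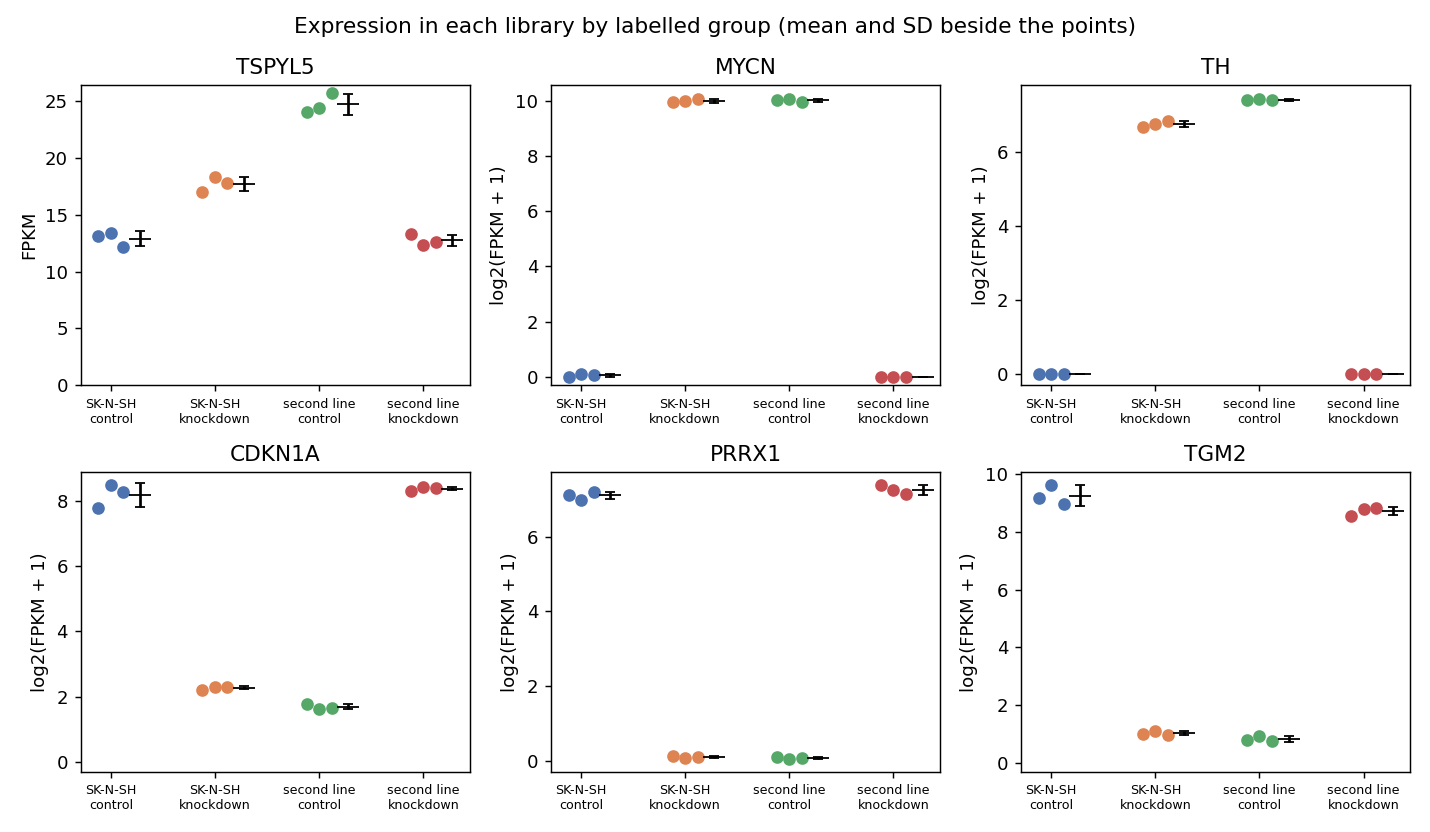
Expression of TSPYL5 in FPKM, and of MYCN, TH, CDKN1A, PRRX1 and TGM2 as log2(FPKM + 1), in each library, with points for the 3 libraries of a labelled group and the mean ± SD beside them. MYCN and TH are high in the libraries labelled SK-N-SH knockdown and second line control, and CDKN1A, PRRX1 and TGM2 in the other groups.

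The first comparison asked which genes differ when SK-N-SH cells carry the hairpin against TSPYL5. The libraries labelled SK-N-SH knockdown had high levels of sympathetic neuroblast genes that were low or unread in the libraries labelled SK-N-SH control. TH, the rate-limiting enzyme of catecholamine synthesis, was read at 108 ± 5.31 FPKM against 0 reads in the 3 controls, at least 6567-fold higher by a floor of 3 reads over the control group. The neuropeptide gene GAL was 615-fold higher (168 ± 14.7 against 0.274 ± 0.0482 FPKM, adjusted p = 4.51e-15), the surface glycoprotein gene CD24 464-fold (184 ± 7.13 against 0.396 ± 0.0322) and the zinc finger gene INSM2 930.1-fold (132 ± 6.35 against 0.142 ± 0.0648). Genes of matrix and mesenchymal cells were lower in the libraries labelled knockdown: the cross-linking enzyme gene TGM2 stood at 1.05 ± 0.0931 against 619 ± 154 FPKM, 587-fold lower, POSTN, which encodes periostin, was 515-fold lower (0.453 ± 0.1004 against 233 ± 37.8) and TGFBI 180.5-fold lower (4.77 ± 0.401 against 860.2 ± 52.3). The amino acid transporter gene SLC38A4 fell from 258 ± 17.9 FPKM in the controls to 0 reads, at least 18048-fold lower, and FAM129A stood at 0.0428 ± 0.0138 against 250.0 ± 21.0 FPKM.

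Genes tied to p53 were mostly lower in the libraries labelled SK-N-SH knockdown. Of 30 tested p53 targets 26 fell, 1 rose and 3 did not pass (camera adjusted p = 2.38e-08, but adjusted p = 0.216 with an estimated correlation). CDKN1A, the p21 cell cycle inhibitor (chromosome 6, 36676460 to 36687339, plus strand, ENSG00000124762), stood at 3.84 ± 0.164 against 295 ± 70.9 FPKM, 76.9-fold lower (log2 fold -5.91, SE 0.14, adjusted p = 5.67e-12). MDM2, the ubiquitin ligase of p53, was 3.05-fold lower (3.89 ± 0.240 against 11.9 ± 2.53) and PHLDA3 202-fold lower. G3BP1 was 1.88-fold higher (24.3 ± 0.716 against 12.9 ± 0.652, adjusted p = 5.32e-09) and RANBP2 1.79-fold higher (16.1 ± 0.926 against 8.98 ± 0.683, adjusted p = 3.07e-07).

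Of the identity lists, 23 of 24 tested noradrenergic genes rose in the libraries labelled SK-N-SH knockdown and 1 fell, with CHGA, the chromogranin of secretory granules, at 303 ± 18.9 against 2.29 ± 0.540 FPKM. Of 26 neuronal genes 24 rose and 1 fell, among them the neurofilament gene NEFM (436-fold higher) and the RNA-binding protein gene ELAVL3 (292-fold). Of 27 mesenchymal genes 23 fell and 2 rose, with the homeobox gene PRRX1 at 0.0693 ± 0.0134 against 137 ± 10.05 FPKM and the receptor kinase gene AXL 183-fold lower. Of 33 matrix and EMT genes 29 fell and 3 rose (adjusted p = 0.291 with an estimated correlation). Stemness genes went both ways, with 10 of 19 higher, CD24 among them, and 8 lower, among them NT5E, the ecto-nucleotidase gene, 28.02-fold (13.8 ± 0.914 against 386 ± 38.8). All 25 tested G2/M genes rose, MKI67 3.85-fold and UBE2C 3.46-fold (adjusted p = 0.493 with an estimated correlation), as did 28 of 29 S phase genes, E2F1 9.66-fold and MCM3 6.22-fold (adjusted p = 0.416 with an estimated correlation). Of 28 MYC target and ribosome biogenesis genes 21 rose, NOLC1 3.98-fold, and 3 fell, among them the lactate dehydrogenase gene LDHA 18.1-fold (adjusted p = 0.448 with an estimated correlation). Interferon response genes fell in 20 of 23, IFITM2 133-fold and IFITM3 43.1-fold, and 3 rose (adjusted p = 0.291 with an estimated correlation). Cholesterol synthesis genes rose in 20 of 23, HMGCS1 11.7-fold, and 3 fell (adjusted p = 0.284 with an estimated correlation). Of 28 stress granule, SUMO and nuclear pore genes 22 rose, the GTPase gene RAN 2.56-fold, and 4 fell, the SUMO ligase gene PIAS3 6.14-fold (adjusted p = 0.416 with an estimated correlation). Markers of epithelial cells fell in 5 of the 6 tested, KRT18 292-fold (0.0591 ± 0.0540 against 17.3 ± 2.96 FPKM, and 484-fold without SK-N-SH knockdown replicate 1) and KRT8 122-fold, and 1 rose (adjusted p = 0.216 with an estimated correlation). Ribosomal protein genes rose in 21 of 30 and fell in 3 (adjusted p = 0.773 with an estimated correlation). The p53 list and the lists of this group other than stemness, 13 in all, passed limma's camera test with a preset correlation of 0.01 at adjusted p from 2.11e-10 to 0.0260. With an estimated correlation the noradrenergic (adjusted p = 0.00906), neuronal (0.0179) and mesenchymal (0.0350) lists passed. The other 10 calls were lost with it. The epithelial call was also lost with a minimum mean FPKM of 2, at adjusted p = 0.0507, the highest of 0.0145 to 0.0507 over the alternatives with camera's preset correlation. IFITM2, IFITM3, KRT8, KRT18, RAN, SET and the ribosomal protein genes have near-identical relatives or pseudogenes whose reads counting can divide, so their levels are uncertain.

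The remaining 8 lists did not pass the camera test in SK-N-SH. Stemness gave adjusted p = 0.639. Of 27 unfolded protein and amino acid stress genes 15 rose and 7 fell (adjusted p = 0.290), with the serine synthesis gene PHGDH 5.01-fold and MTHFD2 4.78-fold higher. Of 26 hypoxia and glycolysis genes 9 rose and 11 fell (0.554), of 20 immediate early genes 9 rose and 9 fell (0.806), and of the 9 tested TSPY and NAP family genes 7 rose and 2 fell (0.127), with SET 2.33-fold higher. Of 15 mitochondrially encoded transcripts 5 rose and 5 fell (0.967). Of the Schwann cell markers 3 were tested, with NGFR 80.2-fold and PMP22 1.71-fold higher and 1 lower (0.430), and the 1 blood and endothelial marker tested rose (0.459). Adjusted over the list alone, the counts of all these lists were the same.

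In total 12648 of 15856 tested genes passed in SK-N-SH, 6458 higher and 6190 lower in the libraries labelled knockdown, and 4926 of them changed at least 2-fold. The direction rests on labels that TSPYL5 contradicts in this line.

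**Figure D3:**
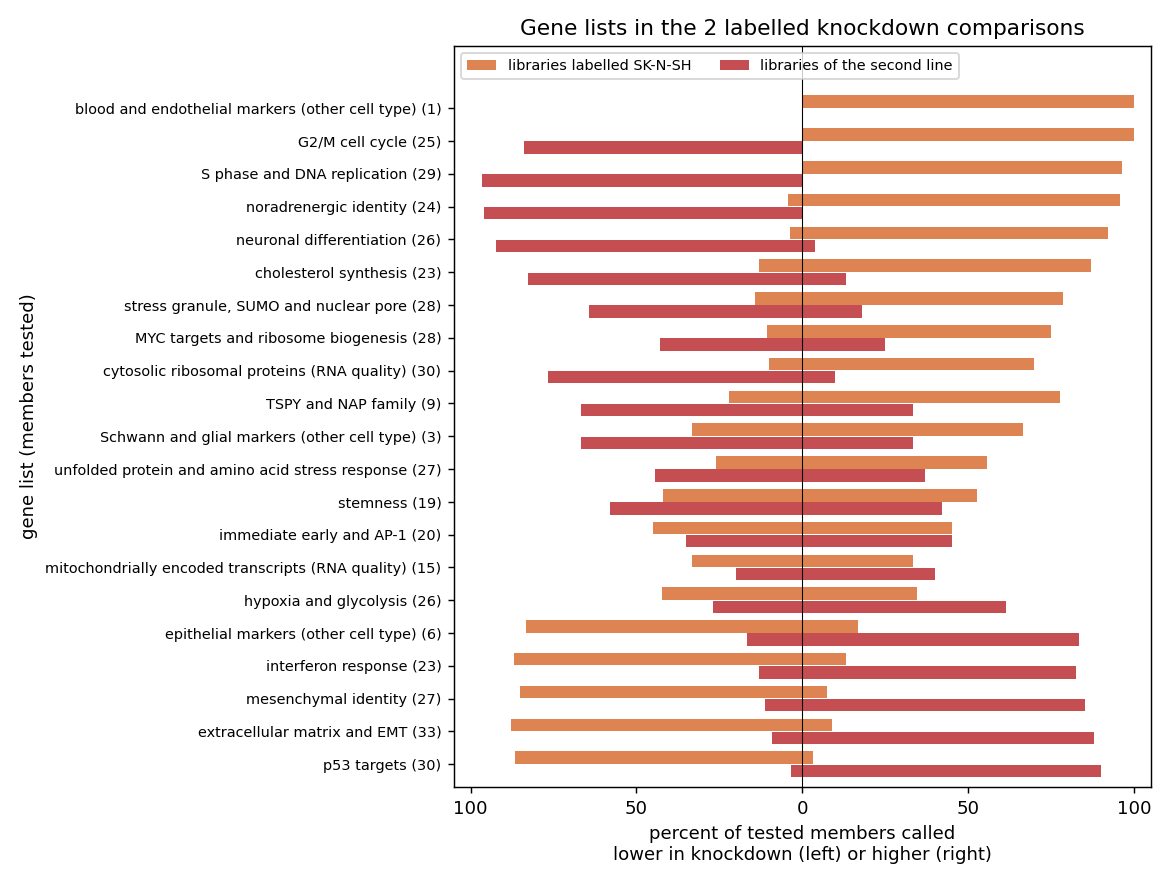
Share of tested members of each gene list called lower (left) or higher (right) in the libraries labelled knockdown, in percent, for SK-N-SH and the second line, with the number tested in brackets. All 25 G2/M genes were higher in SK-N-SH and 21 were lower in the second line, and 26 of 30 p53 targets were lower in SK-N-SH and 27 higher in the second line.

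The next comparison put the same question in the second line, and the directions were the opposite. The libraries labelled knockdown correlated at 0.960 to 0.975 with SK-N-SH control and at 0.692 to 0.721 with their own control. Differences by this label are thus not shown to be responses to the hairpin. POSTN rose from 0.0503 ± 0.0219 FPKM in control to 531 ± 147 in the libraries labelled knockdown, TGM2 rose 537-fold (421 ± 41.6 against 0.784 ± 0.109), the extracellular superoxide dismutase gene SOD3 stood at 221 ± 25.5 against 0.0370 ± 0.0157 FPKM and PRRX1 at 152 ± 12.9 against 0.0501 ± 0.0254. MYCN fell at least 47683-fold and TH at least 9731-fold, each to 0 reads, and the microtubule regulator gene STMN2 was 1435-fold lower (0.368 ± 0.0733 against 528 ± 6.57, adjusted p = 2.34e-16). CHGA stood at 0.0183 ± 0.0179 against 342 ± 4.45 FPKM, GAL at 0.0294 ± 0.0255 against 207 ± 7.32 and CD24 at 0.0251 ± 0.0293 against 179 ± 3.97. MAGEA3 was also among the genes with the largest rise, but reads of its near-identical family members can be split by counting, so its level is uncertain. CDKN1A was 149-fold higher (332 ± 11.996 against 2.23 ± 0.180, log2 fold 6.69, SE 0.14, adjusted p = 1.90e-12), PHLDA3 141-fold and MDM2 2.35-fold (8.98 ± 0.537 against 3.82 ± 0.156). G3BP1 was 1.38-fold lower (18.1 ± 0.340 against 24.9 ± 0.465, adjusted p = 1.96e-06) and RANBP2 2.05-fold lower (7.86 ± 0.429 against 16.1 ± 0.636, adjusted p = 4.59e-08).

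By list, 23 of 24 noradrenergic genes fell in the second line libraries labelled knockdown and 0 rose, and 24 of 26 neuronal genes fell, NEFM from 83.3 ± 5.51 to 0.0127 ± 0.0127 FPKM, while 1 rose. Both calls held with an estimated correlation (adjusted p = 0.00713 and 0.0166). Of 30 p53 targets 27 rose and 1 fell (adjusted p = 0.254 with an estimated correlation). Of 33 matrix genes 29 rose and 3 fell (adjusted p = 0.354 with an estimated correlation). Of 27 mesenchymal genes 23 rose and 3 fell (adjusted p = 0.0510 with an estimated correlation). Of 23 interferon genes 19 rose, IFITM2 132-fold and IFITM3 37.3-fold, and 3 fell (adjusted p = 0.354 with an estimated correlation). Of 6 epithelial markers 5 rose, KRT18 302-fold and KRT8 148-fold, and 1 fell (adjusted p = 0.254 with an estimated correlation). G2/M genes fell in 21 of 25, MKI67 5.26-fold, and rose in 0 (adjusted p = 0.579 with an estimated correlation). S phase genes fell in 28 of 29, E2F1 5.65-fold and the replication licensing gene CDT1 5.16-fold, and rose in 0 (adjusted p = 0.556 with an estimated correlation). Cholesterol synthesis genes fell in 19 of 23 and rose in 3 (adjusted p = 0.310 with an estimated correlation), stress granule, SUMO and nuclear pore genes fell in 18 of 28 and rose in 5 (adjusted p = 0.579 with an estimated correlation), and ribosomal protein genes fell in 23 of 30 and rose in 3 (adjusted p = 0.693 with an estimated correlation). All of these lists passed the camera test with the preset correlation, at adjusted p from 4.27e-11 to 0.0380. The epithelial call, at adjusted p = 0.0380 with the preset correlation, was also lost without second line knockdown replicate 1 (adjusted p = 0.0521), with no filter on low values, with a minimum mean FPKM of 2, among protein-coding genes alone and with voom, and ranged from 0.0239 to 0.0769 over the alternatives with that correlation. MYC target and ribosome biogenesis genes did not pass (7 higher, 12 lower of 28, camera adjusted p = 0.405), nor did stemness genes (8 higher, among them the integrin gene ITGA6 760.0-fold and 1192-fold without second line control replicate 1, and 11 lower of 19, adjusted p = 0.455). The unfolded protein (10 higher, 12 lower of 27), hypoxia (16 higher, 7 lower of 26), immediate early (9 higher, 7 lower of 20), TSPY and NAP family (3 higher, 6 lower of 9), Schwann cell (1 higher, 2 lower of 3) and mitochondrial lists (6 higher, 3 lower of 15) did not pass either, at adjusted p from 0.283 to 0.742. Adjusted over the list alone, 22 G2/M genes fell and 1 noradrenergic gene rose, and the other counts given here were the same. In total 12692 genes passed, 6323 higher and 6369 lower, 5032 of them at least 2-fold on the log2(FPKM + 1) scale.

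The test of the difference between the lines asked whether the hairpin comparison gave the same result in both. It found 13458 of 15856 genes with different effects. The most positive differences (second line minus SK-N-SH, on the log2(FPKM + 1) scale) were those of POSTN at 16.26, TGM2 at 16.09, SLC38A4 at 15.05, FAM129A at 14.48 and TNC, which encodes the matrix protein tenascin C, at 14.30. The most negative were those of MYCN at -19.97, CHGA at -14.94, GAL at -14.71, CD24 at -14.51 and TH at -14.19. Each of these 10 genes had a mean under 1 FPKM in at least 1 group, so the sizes and the order of these differences depend on the pseudocount of 1.

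Genes changed in both lines were mostly changed in opposite directions. Of the 6458 genes higher in SK-N-SH, 5558 were lower in the second line, and of the 6190 lower in SK-N-SH, 5427 were higher in the second line, against 2594 and 2468 for independent lists. The same direction was found for 156 genes higher in both and 116 lower in both, against 2575 and 2486 for independent lists. Across genes the log2 folds of the lines had Pearson's r = -0.945 and Spearman's rho = -0.921, and 88.1% of genes had opposite signs. The 2 comparisons share no library. SK-N-SH knockdown was like second line control, and second line knockdown like SK-N-SH control, so opposite folds had to follow. These overlaps and correlations therefore restate that likeness and are no independent result. Among the genes higher in both were DKK1, a secreted Wnt inhibitor (2.42-fold in SK-N-SH and 2.45-fold in the second line), the phosphatase genes DUSP1 (1.87-fold and 3.88-fold) and DUSP2 (10.3-fold and 2.01-fold), ID3 (2.44-fold and 1.61-fold) and the sphingosine kinase gene SPHK1 (2.09-fold and 2.26-fold). Among those lower in both were MGP, the matrix Gla protein gene (2.45-fold and 4.32-fold), PPL (3.94-fold and 3.28-fold), the sulfotransferase gene SULT1E1 (5.42-fold and 6.85-fold), TENM4 (1.93-fold and 2.78-fold) and RGS11 (1.83-fold and 2.17-fold). A gene can also share a direction through a difference between second line knockdown and SK-N-SH control. DKK1 stood at 20.5 to 32.9 FPKM in SK-N-SH control and 83.5 to 192 in second line knockdown. It stood at 54.9 to 65.4 in SK-N-SH knockdown and 58.3 to 59.2 in second line control. Genes changed the same way are thus not shown to respond to the hairpin.

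**Figure D4:**
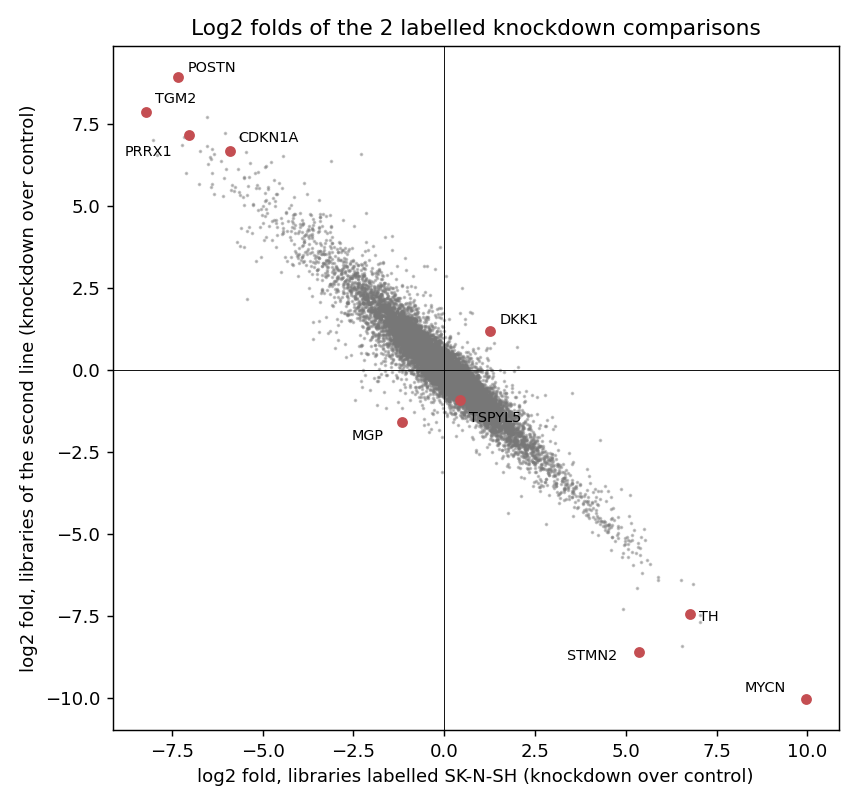
Log2 fold of knockdown over control on the log2(FPKM + 1) scale in the libraries labelled SK-N-SH (horizontal) and in those of the second line (vertical), each point 1 gene, with 10 genes of the text in red. The points follow a falling diagonal (Pearson's r = -0.945), with MYCN at one end and POSTN at the other, and DKK1 and MGP lie off it.

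Comparing the control libraries asked how the lines differ without the hairpin against TSPYL5. Second line control libraries had the neuroblast genes and SK-N-SH control libraries the mesenchymal ones. MYCN stood at 1040.4 ± 33.3 against 0.0408 ± 0.0407 FPKM, and TH at 170.4 ± 3.08 against 0 reads, at least 10356-fold higher in the second line. CHGA was 149-fold higher in the second line, NEFM 541-fold, the intermediate filament gene INA 110.5-fold, CD24 453-fold and NGFR 91.6-fold (5.10 ± 0.909 against 0.0557 ± 0.0197), and PMP22 1.86-fold. AXL was 270.3-fold and NT5E 40.8-fold lower in the second line, and PRRX1 stood at 0.0501 ± 0.0254 against 137 ± 10.05 FPKM. By list, 23 of 24 noradrenergic and 25 of 26 neuronal genes were higher in the second line control and 1 of each lower, 23 of 27 mesenchymal genes were lower and 3 higher, and of 19 stemness genes 11 were higher and 8 lower. Adjusted over the list alone these counts were the same. The p53 targets were lower in 26 of 30 and higher in 1, and 5 of 6 epithelial markers were lower. Of 30 ribosomal protein genes 17 were higher and 3 lower, and of 15 mitochondrially encoded transcripts 5 were higher and 5 lower. In total 12615 genes passed, 6451 higher and 6164 lower, with 4910 changed at least 2-fold on the log2(FPKM + 1) scale. Each group is 1 line, so this compares these cultures.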

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

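The tests of exchanged line names, of TSPYL5 knockdown in each labelled line and of mixed cells were chosen after the result was seen. The tests of other splits were not.

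The effect of the hairpin label differed between the labelled lines for 13458 of the 15856 genes tested, by the limma test of the difference itself. Among all genes tested 84.9% differed. Most of the 57 genes named in the comparisons by label were chosen by large folds in these same data. Their count is therefore no independent result: 51 of the 57 differed. The difference on the log2(FPKM + 1) scale, second line effect minus SK-N-SH effect, was positive for 24 of them: PPL 0.46, SULT1E1 0.80, DUSP1 0.98, MDM2 2.43, KRT8 4.65, PIAS3 4.93, LDHA 8.21, KRT18 8.53, NT5E 9.97, ITGA6 9.996, IFITM3 10.004, AXL 10.81, PHLDA3 11.09, IFITM2 11.93, CDKN1A 12.59, MAGEA3 13.26, TGFBI 14.09, PRRX1 14.20, SOD3 14.28, TNC 14.30, FAM129A 14.48, SLC38A4 15.05, TGM2 16.09, POSTN 16.26. These include the mesenchymal and matrix genes, CDKN1A and MDM2. It was negative for 27: MYCN -19.97, CHGA -14.94, GAL -14.71, CD24 -14.51, TH -14.19, STMN2 -13.96, INSM2 -13.38, NEFM -12.26, ELAVL3 -11.27, INA -8.92, HMGCS1 -6.58, E2F1 -5.55, PHGDH -5.48, CDT1 -4.71, MCM3 -4.68, NGFR -4.65, MTHFD2 -4.19, MKI67 -4.18, NOLC1 -3.37, UBE2C -3.31, SET -2.33, RAN -2.24, PMP22 -2.12, RANBP2 -1.73, TSPYL5 -1.34, G3BP1 -1.30, ID3 -0.59. These include the neuroblast genes, the cell cycle genes and TSPYL5 itself. The sizes of differences of genes with a group mean under 1 FPKM, among them those at 0 reads (MYCN, TH, SLC38A4 and MAGEA3) and CHGA, GAL, CD24, NEFM, ELAVL3, POSTN, FAM129A, PRRX1, SOD3 and KRT8, depend on the pseudocount of 1.

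By list, members past this test in their list's direction numbered 27 of 30 p53 targets, 24 of 27 mesenchymal genes, 29 of 33 matrix genes, 20 of 23 interferon genes and 5 of 6 epithelial markers on the positive side. On the negative side they numbered 23 of 24 noradrenergic, 25 of 26 neuronal, 24 of 25 G2/M, 28 of 29 S phase, 21 of 28 MYC target, 20 of 23 cholesterol synthesis, 22 of 28 stress granule, SUMO and nuclear pore, and 23 of 30 ribosomal protein genes. These 13 lists passed camera with the preset correlation, and with an estimated correlation the noradrenergic (adjusted p = 0.0112), neuronal (adjusted p = 0.0218) and mesenchymal (adjusted p = 0.0412) lists did. The other 10 calls were lost, at adjusted p = 0.257 to 0.692 with an estimated correlation. The epithelial call was also lost with a minimum mean FPKM of 2 (adjusted p = 0.0687), among protein-coding genes alone (0.0505) and with voom (0.0575), and ranged from 0.0232 to 0.0687 over the alternatives at the preset correlation.

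For the opposite differences in the labelled lines, knockdown of TSPYL5 as the source in the libraries labelled SK-N-SH is argued against by the log2 fold of TSPYL5, 0.43. Cells of both lines mixed in the knockdown libraries are argued against because genes abundant in one control and off in the other were kept at a median of 0.0171% of the control level in SK-N-SH (15 genes) and 0% in the second line (6 genes). Knockdown in the second line, where TSPYL5 fell, stays open, since the highest correlation of its knockdown libraries with their own control lying below the lowest with SK-N-SH control (difference -0.240) only restates the pattern. MYCN stood at 1006 to 1072 FPKM in second line control and had 0 reads in every second line knockdown library. TSPYL5 was still read in those knockdown libraries, at 12.4 to 13.3 FPKM, against 12.2 to 13.4 FPKM in SK-N-SH control. Its lower level than in second line control therefore does not by itself show a knockdown. Whether a partial loss of TSPYL5 can take MYCN to 0 reads was not tested. An exchange of line names between 2 of the 4 groups is also an open candidate explanation, as a hypothesis: 176 genes were on (at least 5 FPKM) in all 6 libraries of SK-N-SH knockdown and second line control and off (at most 0.1 FPKM) in the other 6, or the reverse, against 0 when groups were paired by labelled line and 0 when paired by hairpin, counts that restate the likeness of the groups and are no independent support. SK-N-SH is known to lack MYCN amplification, and MYCN stood at 0.0408 ± 0.0407 FPKM in SK-N-SH control and 1028 ± 49.0 in the libraries labelled SK-N-SH knockdown, so under this hypothesis the knockdown groups may be the exchanged ones, with a second line like SK_N_BE2 of the titles, whose name resembles that of a MYCN-amplified line, rather than SH-SY5Y, which is known to lack the amplification.

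Splitting the 6 libraries of SK-N-SH into 3 and 3 gives 10 splits, too few for a share under 0.05: the real split called 12648 genes and the highest other 1. For the second line the real split called 12692 and the highest other 0, and for the control groups 12615 and 0, again with 10 splits each, of which 1, the real one, reached the real count. For the difference between lines, 1 of 100 splits, the real one, gave 13458 genes, and the highest other gave 7802, a share under 0.05. Replicates were far more alike than the groups of a labelled line, so splits that mix groups had to call fewer genes. The share therefore shows that the groups differ as sets of libraries, and not what made them differ.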

How the results depend on the processing

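The comparisons across labelled lines and the voom test were chosen after the data were seen, and the other settings were not. Counts of changed genes in both knockdown comparisons, their difference and the control comparison stayed within 1.5 times under every setting run: 9451 to 16180 in SK-N-SH, 9549 to 16293 in the second line, 9956 to 18493 for the difference and 9463 to 16200 in control, and without single libraries 12226 to 12723, 12292 to 12703, 13258 to 13381 and 12185 to 12676. Genes changed in opposite directions in the labelled lines numbered 10696 to 10871 without single libraries and those in the same direction 214 to 298. The log2 fold of TSPYL5 ranged from 0.39 to 0.46 in SK-N-SH and from -1.03 to -0.87 in the second line. Equal FPKM sums moved the median log2 fold of all genes from -0.02 to -0.12 in the second line and from -0.03 to -0.12 for the difference. Median-of-ratios scaling moved nothing, since the FPKM values already carry it, and the count model was not run.

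Lists past the threshold with camera's preset correlation were 13, 12 and 13 for SK-N-SH, the second line and the difference. With an estimated correlation they were 3, 2 and 3, and 1 and 0 for SK-N-SH knockdown against second line control and second line knockdown against SK-N-SH control, and with fry 20, 19, 20, 3 and 12. Fry asks whether a set moves one way, and does not compare it with other genes.

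The smaller comparison of SK-N-SH knockdown with second line control moved most. Its 854 genes became 1622 with array weights (686 higher, 936 lower, 23 at least 2-fold), and without single libraries ran from 474 to 991 (200 to 418 higher, 274 to 573 lower). They were 510 and 474 without SK-N-SH knockdown replicates 1 and 2, and 515, 486 and 527 without second line control replicates 1, 2 and 3. Its 15 genes changed at least 2-fold became 67 with a pseudocount of 0.1, 9 with a mean FPKM of at least 2 and 70 with voom. The 395 of second line knockdown against SK-N-SH control became 976 with the pseudocount and 1193 with voom, and equal FPKM sums gave 2552 genes higher there against 4261. Calls shared by both cross comparisons were 153 in the same and 201 in the opposite direction, 284 and 461 with array weights, and 73 to 190 and 97 to 246 without single libraries. Lists past the threshold were 5 in each, 3 to 7 and 5 to 9 without single libraries (3 without second line control replicate 3, and 9 and 8 for second line knockdown without SK-N-SH control replicate 1 and SK-N-SH knockdown replicate 3), 8 for SK-N-SH knockdown with voom and 9 for second line knockdown with no filter. For SK-N-SH knockdown against second line control the highest count without 1 library, 991, came without second line knockdown replicate 1. That library is in neither group compared and enters only through the spread that all groups share. The count of this comparison therefore also depends on the spread of groups outside it. The causes of the other moves were not tested.

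Replicate numbers do not pair the samples: same-numbered deviations correlated at -0.0751 to -0.00580 within the labelled lines and at -0.0703 to 0.102 in the groups compared across them. With a replicate block the counts were 12413, 12469, 13329 and 12381 in the comparisons by label, with 13, 12 and 13 lists. The block gave 451 genes (212 higher, 239 lower) and 8 lists in SK-N-SH knockdown against second line control, with 71 shared calls in the same and 113 in the opposite direction. The simulation recovered 44.0% of 1.5-fold changes in SK-N-SH and 38% in the second line. Few genes were changed in it, so its adjusted threshold was stricter than in the real comparisons, where 79.8% and 80.0% of genes passed. These shares therefore do not give the sensitivity of the real comparisons by label.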

Other observations

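The comparisons in this part, and the test of a halved TSPYL5 transcript, were chosen after the expression levels of the groups were seen, while the tests of a shared response, of gene length and of splits were written before their results. Each sets the libraries labelled knockdown of one line against the control libraries of the other label, since those groups had like profiles. Culture and hairpin cannot be separated in either comparison.

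In the libraries labelled SK-N-SH knockdown against second line control, the groups with high MYCN, neuronal genes were lower. Of 26 tested neuronal genes 14 fell and 0 rose (camera adjusted p = 3.43e-14, and adjusted p = 0.0121 with an estimated correlation), among them STMN4, a microtubule regulator (2.08-fold, 5.01 ± 0.609 against 10.4 ± 0.129 FPKM), and SNAP25, part of the synaptic vesicle fusion complex (1.71-fold). Adjusted over the list alone 21 fell and 2 rose. On the log2(FPKM + 1) scale the largest falls were those of ITM2A (3.60-fold, 1.70 ± 0.464 against 6.13 ± 0.183), the neuropeptide gene VIP (3.47-fold), the glutamate receptor gene GRIN1 (2.81-fold), GFRA3 (3.08-fold) and SYTL4 (4.57-fold). The largest rises on that scale were those of the cell surface proteoglycan gene GPC3 (4.84-fold, 5.21 ± 0.0740 against 1.08 ± 0.0417), MOXD1 (3.18-fold), IGFBP7 (2.16-fold), DRGX (2.46-fold) and FGFRL1 (2.29-fold). KIT was 1.96-fold and JUN 2.05-fold lower. Of 27 mesenchymal genes 5 rose and 0 fell (adjusted p = 0.00508, and adjusted p = 0.433 with an estimated correlation), NOTCH3 1.85-fold, and adjusted over the list alone 8 rose and 1 fell. Of 23 cholesterol synthesis genes 1 rose and 2 fell (adjusted p = 0.000503, and adjusted p = 0.610 with an estimated correlation), and 1 and 6 adjusted over the list alone. The unfolded protein and ribosomal protein lists passed with 0 members past the test (adjusted p = 0.0160 and 0.0496, and adjusted p = 0.904 for both with an estimated correlation). The former was lost without SK-N-SH knockdown replicate 2 (0.0678) and second line control replicate 3 (0.193), with 0.00253 to 0.193 over the alternatives at the preset correlation. The latter ranged from 0.000219 to 0.887, and was lost without SK-N-SH control replicate 2 (0.0558), SK-N-SH knockdown replicate 3 (0.887), second line control replicates 1 (0.0557) and 3 (0.406) and second line knockdown replicate 3 (0.0646), and with quantile normalization (0.608), array weights (0.210) and no intensity trend (0.0504). In all 854 genes passed in limma, 359 higher and 495 lower, and 15 of them changed at least 2-fold on the log2(FPKM + 1) scale. That scale leaves out FGFRL1, STMN4 and JUN, whose ratios of mean FPKM are over 2-fold. Without SK-N-SH knockdown replicate 2 the count of genes that passed was 474, the lowest without any 1 library.

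In the libraries labelled second line knockdown against SK-N-SH control, the groups with little or no MYCN, genes of ribosome biogenesis and DNA replication were higher. Of 28 MYC target and ribosome biogenesis genes 23 rose and 0 fell (camera adjusted p = 4.48e-08, and adjusted p = 0.660 with an estimated correlation), RRP9 1.98-fold and DKC1, the pseudouridine synthase dyskerin, 1.86-fold (40.8 ± 0.2001 against 21.9 ± 1.87 FPKM). Of 29 S phase genes 19 rose and 0 fell (adjusted p = 2.03e-05, and adjusted p = 0.713 with an estimated correlation), CDC6 2.43-fold and CCNE1 2.28-fold, with 22 higher adjusted over the list alone. Of 24 noradrenergic genes 14 fell and 2 rose (adjusted p = 0.000153, and adjusted p = 0.159 with an estimated correlation), PHOX2A from 9.22 ± 2.81 to 0.920 ± 0.289 FPKM. Of 23 interferon genes 9 fell and 3 rose (adjusted p = 0.00725, and adjusted p = 0.713 with an estimated correlation), IFI44 2.34-fold and STAT2 1.76-fold lower. Of 30 ribosomal protein genes 9 fell and 0 rose, and 4 adjusted over the list alone (adjusted p = 0.000153, and adjusted p = 0.718 with an estimated correlation). Of 15 mitochondrially encoded transcripts, a sign of RNA quality, 6 rose and 0 fell. That list did not pass (adjusted p = 0.0682, and adjusted p = 0.761 with an estimated correlation), but passed with voom (0.0201), no intensity trend (0.0349) and equal FPKM sums (0.0459), and without SK-N-SH knockdown replicates 1 (0.0447) and 3 (0.0278) and second line knockdown replicate 1 (0.0441), with 0.0201 to 0.371 over the alternatives at the preset correlation. On the log2(FPKM + 1) scale the largest rises were those of the BMP antagonist gene NOG (24.3-fold, 97.9 ± 19.8 against 4.03 ± 0.821), STC1 (103-fold), ANKRD1 (8.03-fold) and the EGF family gene HBEGF (13.8-fold), with SPANXD, a member of a near-identical family and therefore uncertain. Second line knockdown replicate 1 stood apart, with a chi-square per gene of 21.2 and 15.9 against replicates 2 and 3, which gave 5.68 between them. In replicate 1 ANKRD1 stood at 90.1 FPKM against 287 and 247 in replicates 2 and 3. HBEGF stood at 7.98 against 24.0 and 18.2, and STC1 at 5.18 against 10.2 and 9.83. The largest falls on that scale were those of the Wnt inhibitor gene DKK2 (10.9-fold, 4.95 ± 0.917 against 54.1 ± 5.95), STMN2 (31.4-fold), MGP (15.0-fold), SULT1E1 (36.9-fold) and CD248 (19.7-fold, and 36.5-fold without second line knockdown replicate 1). INA was 6.99-fold, TGFB2 7.63-fold and DUSP1 7.73-fold higher, and the matrix genes DCN 35.7-fold and COL6A3 7.54-fold lower. In all 6996 genes passed in limma, 4261 higher and 2735 lower (60.9% higher), and with equal FPKM sums 2552 were higher and 3919 lower (39.4% higher).

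Among the genes fixed by name, G3BP1 was 1.40-fold higher in second line knockdown than in SK-N-SH control (adjusted p = 2.48e-05). MDM2 was 1.32-fold lower there (adjusted p = 0.0327, and 0.000167 to 0.128 over the alternatives), a call lost with no filter on low values (0.0755) and without SK-N-SH control replicates 2 (0.120) and 3 (0.128) and second line knockdown replicates 1 (0.0799) and 2 (0.0865). RANBP2 was 1.14-fold lower (adjusted p = 0.0466, and 0.00736 to 0.166 over the alternatives), lost with no filter (0.0810), no intensity trend (0.0580), array weights (0.118) and a replicate block (0.102), and without SK-N-SH control replicates 1 (0.166) and 3 (0.0666), SK-N-SH knockdown replicate 2 (0.0632), second line control replicates 1 (0.0558), 2 (0.0628) and 3 (0.0538) and second line knockdown replicates 1 (0.123) and 2 (0.118). CDKN1A gave a log2 fold of 0.20 (adjusted p = 0.278, and 0.0386 to 0.966 over the alternatives) that passed without SK-N-SH control replicate 2 (0.0386), and MYCN one of -0.06 (adjusted p = 0.362, and 0.0400 to 0.708 over the alternatives) that passed with a pseudocount of 0.1 (0.0400). In SK-N-SH knockdown against second line control CDKN1A was 1.72-fold higher (adjusted p = 0.0316, and 0.000723 to 0.107 over the alternatives). That call was lost with no filter (0.0717), with voom (0.0779), without SK-N-SH knockdown replicates 1 (0.0755), 2 (0.107) and 3 (0.0881) and without second line control replicates 1 (0.0657), 2 (0.105) and 3 (0.103). The log2 folds of G3BP1 (-0.04), RANBP2 (-0.01), MYCN (-0.02) and MDM2 (0.02) did not pass there, at adjusted p from 0.764 to 0.984.

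TSPYL5 was 1.40-fold lower in the libraries labelled SK-N-SH knockdown than in second line control (log2 fold -0.46, SE 0.05, limma adjusted p = 0.000444), lower in 3 of 3 libraries, so here the target gene goes with its label. Between second line knockdown and SK-N-SH control the log2 fold was -0.01 (adjusted p = 0.880), and its 95% confidence interval ran from -0.122 to 0.10, which excludes a TSPYL5 transcript at 0.5 of the control level. If the line names of 2 groups were exchanged, which is a hypothesis, TSPYL5 mRNA would be partly reduced in one line and not detectably in the other. Protein was not measured, so a loss of TSPYL5 protein stays open. Equal FPKM sums gave the lowest log2 fold between second line knockdown and SK-N-SH control, -0.15.

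A response to the hairpin shared by both cross comparisons was tested by the log2 folds across the 15856 genes, which are not independent replicates. Pearson's r was -0.0706 (Spearman's rho -0.0947), and -0.109 to -0.0374 without single libraries. In SK-N-SH knockdown against second line control 854 of 15856 genes passed. Most of its folds were thus not told apart from the spread between libraries, which weakens r. Shared calls, given below, also did not exceed those for independent lists in the same direction. Together these argue against one response making up most of the differences in both. A smaller shared response could be masked by differences between the cultures, so it stays open. A trend with gene length is argued against as the whole source of the larger comparison, since 6888 genes passed after its removal and 6996 before, 6182 of them in both (923 and 854 in the smaller one, 830 in both). Shared calls numbered 76 higher and 77 lower in both, against 96.5 and 85.4 for independent lists. In opposite directions 93 genes were higher in the first and lower in the second, and 108 the reverse, against 61.9 and 133. Among genes with the same direction in both, FGFRL1, AQP1, B4GALT6, VEGFC and STEAP3 were higher and FLRT3, HAS2, ADD3, NSG2 and MSX2 lower. What differs within each pair may come from the hairpin, from the cultures or from their passage, and these stay open.

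Each of these comparisons has 10 splits of 3 and 3, too few for a share under 0.05. The real split called 854 genes and the highest other 2 in the first, and 6996 and 2 in the second, and 1 split, the real one, reached the real count in each.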
